A study of Mus musculus with 4 samples.

How the data were processed

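RNA from the prostates of 4 mice aged 60 days, on a mixed strain background, was measured on 4 two-colour Agilent mouse arrays. Per the labels, the red Cy5 channel of each array held the RNA of 1 mouse and the green Cy3 channel held a pool of RNA from 3 wild-type mice. The dyes were not swapped. All 4 mice carried conditional Trp53 deletion through the probasin-driven Cre transgene PB-Cre4. In 2 mice, called mutant here, 1 Rb1 allele coded for the R654W protein and the other was the conditional allele. In the other 2 mice, called null here, both Rb1 alleles were conditional.

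The deposited scanner files give the spot brightness as intensity, as mean signals, background medians and processed signals, per the file headers. Per the file headers the images were read with Agilent Feature Extraction 9.5.1.1, while the submitters' processing notes name version 8.5. Per the file headers the processed signals were background-subtracted and dye-normalised within each array. The deposited log10 ratio equalled the log10 of red over green processed signal, within 1e-04, at all 119488 spot readings with no surrogate signal. It was 0 at all 39239 readings where both channels used a surrogate and at 3302 of the 14789 where 1 channel did. The authors' deposited table gives group means as a linear ratio for 26174 rows, with no value per array and no p-value. Its smallest ratio of the group means was 1.13. Among accessions found once in both, 7226 genes were also tested here. Over these, the authors' deposited table and the fitted log2 change here had a Spearman correlation of 0.86. With no ratio under 1.13, genes near no change are missing, which can raise such a correlation.

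Mean signals were corrected against background medians with normexp (offset 50) and normalised within each array by loess in limma 3.58.1 under R 4.3.3. Control spots had weight 0 and spots carrying an outlier flag were left out. No spot was saturated. Each array had 43379 spots that were not controls, for 41174 probes. A probe was kept when the mouse channel was well above background on both arrays of a genotype, or the pool channel on all 4 arrays. This left 24851 probes, and the probe of highest mean intensity stood for each gene, giving 16826 gene rows. Gene names came from the accession for 22951 probes, from a current symbol for 6659 and from a unique older symbol for 3109, using the RefSeq table of the GRCm38.p6 assembly. The other 8455 probes kept the name in the file. Probe positions given here are those of the files, in build mm7. Coordinates of the RefSeq table served only to order genes along chromosomes for the tests of neighbouring genes.

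The log2 ratios of the 4 arrays were fitted with lmFit and eBayes in limma with a term for each genotype. Mutant was compared with null, and each genotype with the pool by testing its mean ratio against 0. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. The pool counts as 1 control sample, so tests against it leave out the spread between wild-type mice, and an unequal response of the dyes to a gene stays in them. A constant dye effect cancels between the genotypes. One that varies with the brightness of an array cancels only as far as loess removed it. The labels name individual mice, with 2 per genotype. All 4 arrays came from 1 slide and 1 scan, with a genotype on neighbouring positions, so position and genotype cannot be told apart. An exact permutation of 2 against 2 arrays cannot go below p = 0.333.

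The 26 gene lists, the comparisons and the rule for named genes were fixed before the data were examined. So were the alternatives, except where one is named below as added later. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, which tests whether the genes of a list move one way on balance. Named genes were the 10 largest rises and falls past the threshold that agreed on all arrays concerned. Between the genotypes, a direction with fewer than 5 such genes was filled up to 5 by the smallest unadjusted p among genes whose arrays did not overlap. For each list the rule took up to 4 members past the threshold, or else the 2 brightest. Rb1, Trp53, Rbl1, Rbl2, E2f1, E2f2, E2f3, Cdkn1a and Cdkn2a were always included. Names without a gene symbol were passed over. Not every gene the rule took is reported here. A fold given as "at least" sets the brighter genotype against the lowest signal well above background, per channel after loess and Aquantile, and is open to dye bias.

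The fit was tested on simulated data for mutant against null over 16826 genes. It recovered 0 of 50 genes changed 2-fold, 21 of 50 changed 4-fold, 42 of 50 changed 8-fold and 44 of 50 changed 16-fold. Over 15 draws with variances from the fitted prior, 3.76% of calls were false, and 8.32% with variances taken from the shrunken estimates. Unadjusted p was under 0.05 for 4.98% of unchanged simulated genes, against 1.97% of all genes in the data. The simulation thus differs from these arrays, and recovery and false calls may differ on them. The list test was tested on unchanged genotypes, a check added after the data were seen. With independent genes it called 0.3 of 26 lists per draw on average. The list means differed between mice of a genotype with an SD of 0.518 on the log2 scale. The seminal vesicle list alone had 1.64, the SD without it was 0.415 and the median over lists was 0.267. A shift shared by the genes of a list on an array was drawn with each of these sizes for every list, or with the list's own. In 20 draws the preset test called 12 to 20 of the 26 lists at 0.518, 10 to 20 at 0.415, 5 to 17 at 0.267 and 6 to 17 with each list's own SD. The test with an estimated correlation, run at 0.518 and with each list's own SD, called 0. It rests on the few residual degrees of freedom that these arrays leave and has little power. A call lost with it therefore does not show that a list is unchanged. Settings varied were the background correction, normalisation, filter, probe rule, moderation, replicate block, each array left out, the definition of a call and the red channel alone.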

Results

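Gene expression was profiled in the prostates of 2 mutant mice, with the R654W form of the retinoblastoma protein over a conditional allele, and 2 null mice, with conditional loss of Rb1. All 4 were also conditional for Trp53. The design asks how a partly functional retinoblastoma protein compares with its loss, and how each compares with wild-type prostate. The mouse channel was well above background at 26119 and 25528 probes in mutant mice 1 and 2, and at 22168 and 25034 in null mice 1 and 2. The median background-subtracted red signal was 20.5 in null mouse 1, against 90.1, 81.9 and 55.1 in mutant mouse 1, mutant mouse 2 and null mouse 2. The pool channel lay between 24.2 and 24.9 on the 4 arrays. Across genes, the log2 ratios of the mutant mice correlated at r = 0.49 and those of the null mice at r = 0.148. Null mouse 2 correlated at 0.551 and 0.587 with mutant mice 1 and 2, and null mouse 1 at 0.226 and 0.21. Genes are not independent replicates. The number of arrays limits the precision of every value.

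The targeted genes came first. Rb1 had a log2 ratio to the pool of -0.65 and -0.24 in mutant mice 1 and 2, and 0.09 and -0.87 in null mice 1 and 2. Its probe lies on chromosome 14 at 67877318 to 67877377 (mm7). Trp53, read by a probe on chromosome 11 at 69662031 to 69662089, was at 0.14, 0.12, 0.53 and 0.08 in the same order. A second Trp53 probe at 69671206 to 69671265 gave -0.08, -0.27, -0.05 and -0.40. Whether these probes lie in the deleted parts is not established here, and Cre acts in only part of the tissue, so the values do not check the labels. The Rb relative Rbl1 was at 0.38 and 0.56 in the mutant mice and at -0.22 and 0.35 in the null mice. Rbl2 was at -0.28, 0.25, -0.58 and 0.11 across mutant mice 1 and 2 and null mice 1 and 2. The transcription factor E2f1 was at 0.27, 0.52, -0.30 and 0.36, E2f2 at 1.15, 0.63, 0.22 and 0.75, and E2f3 at 1.07, 0.74, 1.52 and 0.68, each by the brightest probe. A second E2f1 probe gave 0.02, -0.07, -0.12 and 0.06. Of the other E2f3 probes past the filter, 1 gave 0.05, 0.12, 0.32 and -0.08 and 1 gave -0.11, 0.05, 0.48 and 0.11, so the higher E2f3 values rest on 1 probe. The cell cycle inhibitor Cdkn1a was at -0.26 and -0.75 in the mutant mice and at 1.11 and -0.71 in the null mice. Cdkn2a did not pass the filter on dim probes. None of these genes passed the threshold in limma in any of the 3 comparisons.

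Between mutant and null prostate no gene of 16826 passed the threshold in limma, with a smallest adjusted p of 0.992. The values that follow belong to genes of smallest unadjusted p whose arrays did not overlap, and none is past the threshold. D17H6S56E-5 had a mean log2 ratio of 0.91 ± 0.26 (SD, n = 2) in mutant mice and -1.32 ± 0.09 in null mice, a difference of 2.23 (SE 0.22). H2-Eb1, an MHC class II chain, was at 0.95 ± 0.11 and -0.57 ± 0.09. Ifi203, of the interferon-inducible family, was at 0.60 ± 0.42 and -1.0 ± 0.08, and Rbm45 at 0.19 ± 0.12 and -1.11 ± 0.37. Rab44 was not well above background on either null array and was at least 2.09-fold brighter in the mutant mice. In the other direction, the histone demethylase gene Kdm5b was at -0.73 ± 0.36 in mutant and 0.62 ± 0.24 in null mice. Dact2 was at -0.45 ± 0.03 and 0.67 ± 0.13, and Klhl42 at -0.22 ± 0.01 and 0.90 ± 0.10. Inhbb, an inhibin and activin subunit, was at 0.15 ± 0.16 and 1.08 ± 0.01, and the histidine decarboxylase gene Hdc at -0.76 ± 0.02 and 0.12 ± 0.06. A second probe of D17H6S56E-5 also differed, by 1.54. Second probes showed little of the change or an opposite sign for Ifi203 (-0.17), Klhl42 (0.02) and Kdm5b (-0.03). In that order they were dimmer, at mean log2 intensities of 7.155, 6.997 and 7.359 against 9.879, 8.337 and 10.21.

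**Figure D1:**
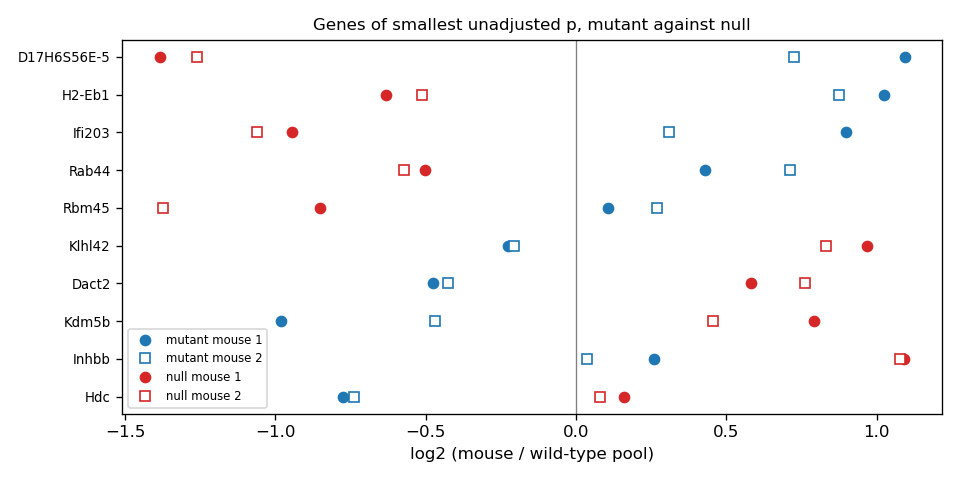
Log2 ratio of each mouse to the wild-type pool (horizontal axis) for the 10 genes of smallest unadjusted p between mutant (blue) and null (red) mice, with filled circles for mouse 1 and open squares for mouse 2. The mice of each genotype lie apart for every gene shown, which is how the genes were chosen, and none passed the threshold.

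At an unadjusted p under 0.05 there were 332 genes, 155 higher and 177 lower in mutant mice, where 841 would be expected by chance. Arrays of the genotypes did not overlap for 29.5% of genes, and chance gives 33.3%. Without null mouse 2, which leaves null mouse 1 alone, 163 genes passed the threshold.

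Of the 26 gene lists, 8 passed the preset test between mutant and null prostate. Smooth muscle genes were lower in mutant mice, with a median log2 difference of -0.57 over 16 genes (camera adjusted p = 1.29e-08). For 12 of them the arrays did not overlap, where chance gives 33.3% over both directions and the share over all genes was 29.5%. Their estimated correlation was 0.653, so these genes moved together and are not separate observations. Cnn1, a smooth muscle calponin, was at -0.31 ± 0.32 in mutant and 0.35 ± 0.24 in null mice (SD, n = 2), and Tpm2 at -1.10 ± 0.26 and -0.19 ± 0.54. Basal epithelial genes had a median difference of -0.43 over 16 genes, immediate early genes -0.35 over 17, and endoplasmic reticulum stress genes -0.55 over 20. For these lists, in that order, null mouse 1 had medians of 0.55, 0.26 and 0.99 and null mouse 2 of -0.18, -0.04 and -0.10. Null mouse 2 was close to the mutant mice, at -0.24 and -0.21, -0.16 and -0.02, and -0.16 and 0.13. Androgen-regulated and prostate secretory genes were higher in mutant mice by a median of 0.31 over 24 genes. Among them Pbsn, the prostate secretory protein probasin, was at 1.05 ± 0.19 in mutant and 0.07 ± 0.39 in null mice. G1/S and DNA replication genes were higher by 0.17 over 47 genes, neuroendocrine genes by 0.25 over 24 (medians of -0.44 and 0.26 in mutant mice 1 and 2) and adipocyte genes by 0.72 over 11. For G1/S genes null mouse 2, at 0.50, lay above both mutant mice, at 0.39 and 0.42, and null mouse 1 was at -0.06. The arrays did not overlap for 2 G1/S genes higher and 3 lower in mutant mice. They did not overlap for 0 higher and 1 lower neuroendocrine gene, and for 0 adipocyte genes. No member of any list passed the threshold over all genes or adjusted over the list alone.

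All 8 calls were lost with an estimated correlation (adjusted p = 0.859 to 0.897) and with fry (adjusted p = 0.98). The test with an estimated correlation has little power with so few arrays, so its losses do not show unchanged lists. In simulated unchanged genotypes whose list means varied between mice, each list by its own spread, 6 to 17 lists were called, so 8 calls are no more than such variation gave. Without null mouse 1, whose medians for endoplasmic reticulum stress and smooth muscle genes were 0.99 and 0.39, 1 of the 8 lists was still called in the same direction and 4 kept their direction.

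**Figure D2:**
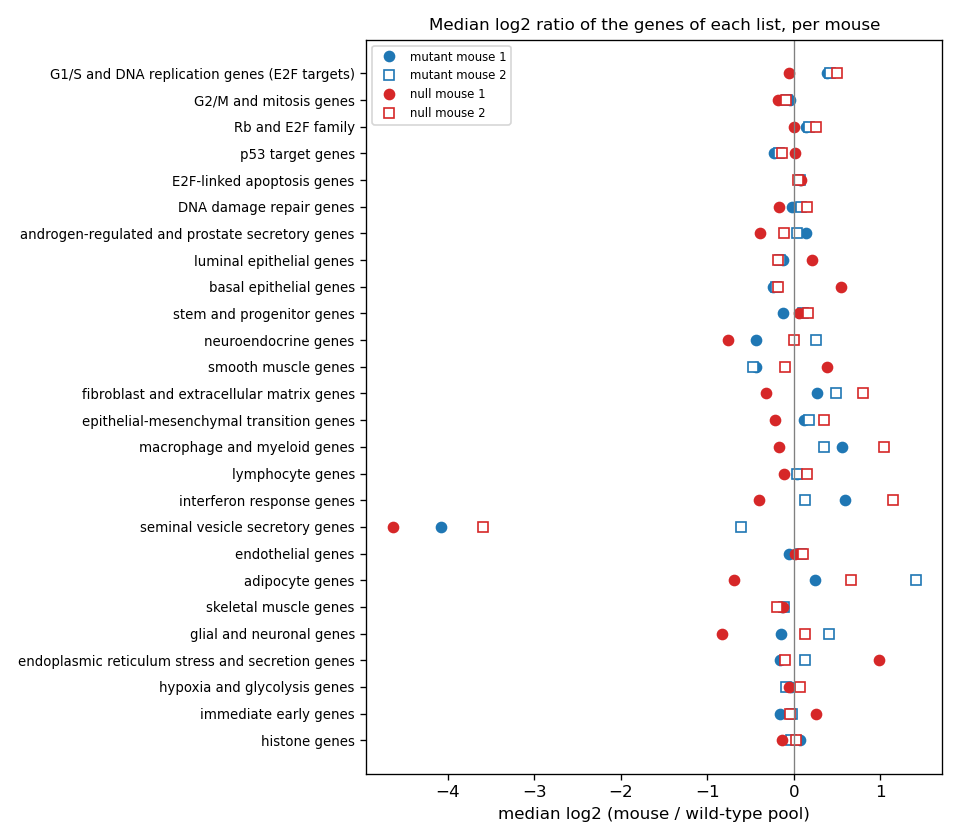
Median log2 ratio to the wild-type pool (horizontal axis) over the genes of each of the 26 lists, for mutant (blue) and null (red) mice, with filled circles for mouse 1 and open squares for mouse 2. For smooth muscle genes null mouse 1 is at 0.39 and null mouse 2 at -0.10, and for interferon response genes they are at -0.41 and 1.15.

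Against the wild-type pool, no gene in null prostate passed the threshold in limma, and 1669 genes had an unadjusted p under 0.05, where 841 would be expected by chance. The seminal vesicle secretory genes stood lowest, with a median log2 ratio of -4.29 over 6 genes (camera adjusted p = 0.000453), and 4 of the 6 passed when adjusted over the list alone. Svs5 was at -4.86 ± 1.61 (SD, n = 2) and Svs2 at -3.72 ± 0.38. Macrophage and myeloid genes were higher by a median of 0.35 over 26 genes, and interferon response genes by 0.39 over 27. The macrophage lysozyme gene Lyz2 was at -1.22 in null mouse 1 and 1.86 in null mouse 2. G1/S and DNA replication genes were higher by 0.24 over 47 genes, and Pcna, the replication clamp, was at 0.72 ± 0.10. Lower medians were found for G2/M genes (-0.16 over 37), neuroendocrine genes (-0.42 over 24), skeletal muscle genes (-0.17 over 14) and androgen-regulated and prostate secretory genes (-0.28 over 24). All 8 calls were lost with an estimated correlation (adjusted p = 0.867), a test of little power here, and fry kept skeletal muscle genes (adjusted p = 0.0475). For G2/M and skeletal muscle genes the estimated correlations, 0.00937 and -0.0721, lay under the preset 0.01, so a larger correlation did not cause those losses. The null mice differed: the medians of null mice 1 and 2 were -0.18 and 1.04 for macrophage, -0.06 and 0.50 for G1/S and -0.41 and 1.15 for interferon response genes. For neuroendocrine genes they were -0.76 and 0.00, and for androgen-regulated and prostate secretory genes -0.39 and -0.12. Without null mouse 2, 559 genes passed the threshold, 3 of the 8 lists were still called in the same direction, 5 kept their direction, and the interferon list was called lower.

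Mutant prostate against the wild-type pool gave 2 genes past the threshold in limma, both lower, and 1715 with an unadjusted p under 0.05. Ms4a5 was at -4.35 ± 0.12 (SD, n = 2, adjusted p = 0.0356) and Naip5, a sensor of bacterial flagellin, at -3.13 ± 0.15 (adjusted p = 0.0431). In null mice they were at -3.96 ± 0.40 and -2.81 ± 0.25, with adjusted p of 0.0569 and 0.0742 there. The differences between the genotypes, -0.39 (SE 0.26) and -0.32 (SE 0.22), did not pass the threshold. Neither was called from Agilent processed signals, where no gene passed, and leaving out either mutant mouse gave 0 genes. With median centring in place of loess, 2778 genes passed, 2764 of them higher, while the median of all genes moved to 0.68 on the log2 scale.

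Of the lists, 10 passed in mutant prostate against the pool. G1/S and DNA replication genes were higher by a median of 0.38 over 47 genes (camera adjusted p = 3e-08). Both mutant mice were above 0 for 35 and below 0 for 2, where both were on the same side of 0 for 66.1% of all genes. The estimated correlation of these genes was 0.545, so they are not separate observations. Pcna was at 0.78 ± 0.08 (SD, n = 2). Macrophage and myeloid genes were higher by 0.48 over 26 genes, fibroblast and extracellular matrix genes by 0.31 over 25 and interferon response genes by 0.36 over 27. The medians of mutant mice 1 and 2 were 0.59 and 0.13 for interferon response genes, 0.56 and 0.35 for macrophage genes and 0.27 and 0.49 for fibroblast genes. The interferon list was not called without mutant mouse 1, nor the fibroblast list without mutant mouse 2. Lyz2 was at 1.42 ± 0.24 and the cathepsin gene Ctss at 0.97 ± 0.17. Smooth muscle genes were lower by a median of -0.40 over 16 genes, 15 of them below 0 in both mice. Lower medians were also found for p53 targets (-0.17 over 31), basal epithelial genes (-0.20 over 16), luminal epithelial genes (-0.20 over 21), skeletal muscle genes (-0.18 over 14) and seminal vesicle genes (-2.40 over 6). Leaving out either mutant mouse kept 7 of the 10 calls, and all 10 lists kept their direction. Within the last list, Svs5 was at -4.68 in mutant mouse 1 and -0.09 in mutant mouse 2. All 10 calls were lost with an estimated correlation (adjusted p = 0.908) and with fry (adjusted p = 0.883). For p53 targets and skeletal muscle genes the estimated correlations, 0.00899 and -0.0721, lay under the preset 0.01. A larger correlation did not cause those losses.

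Changes against the pool in the mutant and null mice correlated at r = 0.522 across genes. Unchanged genotypes sharing a pool of 3 animals gave 0.4 in simulation with independent genes (SD 0.0112 over 50 draws). The covariance was 0.0598, against 0.0288 in simulation. Genes with an unadjusted p under 0.05 in both numbered 278 higher in both, 268 lower in both and 10 in opposite directions. Simulation gave 227.8, 222.3 and 40.6 (SD 15.4, 16.6 and 7.27), and independent lists would give 52.3 and 33.5 in the same direction. The shared direction with all 4 arrays was larger than in that simulation, but by the correlation this rested on null mouse 2. Without that mouse the correlation was 0.253, and without null mouse 1 it was 0.651, where simulation with 3 arrays gave 0.317. Null mouse 1 had the widest log2 ratios (SD 0.56 across genes, against 0.31 to 0.44 in the other mice). A wider spread lowers a correlation at a given covariance. The covariance without null mouse 2 is not given here, so an excess over the shared pool is neither established nor excluded. The draws also leave out genes moving together, so their SD does not give the spread between mice. The shared pool could not be split and the dyes were not swapped, so the part of each stays open. All 4 mice were also conditional for Trp53 and carried Cre, unlike the wild-type pool. Strain differences between these mice, on a mixed background, and the pool were not measured. Against the pool, none of these can be told apart from Rb1.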

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

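All tests of explanations in this part except the one on genes beside Rb1 were chosen after the result was seen. The 8 lists whose mutant and null values differed by the preset list test had median log2 differences, mutant minus null, of 0.17 for G1/S and DNA replication, 0.31 for androgen-regulated and prostate secretory, -0.43 for basal epithelial, 0.25 for neuroendocrine, -0.57 for smooth muscle, 0.72 for adipocyte, -0.55 for endoplasmic reticulum stress and -0.35 for immediate early genes. None held with an estimated correlation, a test of little power here. Without null mouse 1, 4 of the 8 kept their direction. G1/S genes were at a median of 0.50 in null mouse 2, above both mutant mice.

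Null mouse 1 stood apart. Heat shock genes, a list written after Hspa1a was seen to be high, had a median log2 ratio of 2.44 there over 21 genes, with Hspa1a at 5.89, Hsph1 at 4.81 and Dnajb1 at 3.66. Low brightness alone is argued against, since the highest of 10000 random lists of equally bright genes reached 0.48. Those lists held unrelated genes, while this list was chosen through a gene high on that array. Poor RNA or labelling of that dim sample was not tested and stays open. Loss of Rb1 as the whole cause is argued against by a median of 0.18 in null mouse 2. Stress or delay in handling the tissue may account for it and stays open: immediate early genes lay 0.34 above the mean of the other mice, between the bounds set for and against.

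Seminal vesicle genes had medians of -4.08, -4.64 and -3.59 in mutant mouse 1 and null mice 1 and 2, and of -0.61 in mutant mouse 2, where Svs4 was still at -2.50. Unequal amounts of seminal vesicle tissue among mice and pool could give this and stay open: the 4 brighter genes of the list were higher in mutant mouse 2 than in mutant mouse 1 by 1.63 to 4.75, a range of 3.12, where 1 amount of tissue would move them alike, and Ceacam10 was above the pool in all 4 mice. A general loss of secretory gene expression is argued against in mutant mouse 1 and null mouse 2, where prostate secretory genes had medians of 0.14 and -0.12 and lower quartiles of -0.34 and -0.22. It stays open in null mouse 1, at -0.39 with a lower quartile of -1.30, and how far prostate itself expresses the seminal vesicle genes was not tested. Between mutant and null mice the list had a median difference of 1.46 and was not called (camera adjusted p = 0.0639), and it was at -0.37 without mutant mouse 2.

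The genes of smallest p between the genotypes were tight within each genotype, which ranking by p favours. Some are neighbours, such as D17H6S56E-5 and Vars, the latter named after its values were seen. The probes of D17H6S56E-5 and H2-Eb1 both lie on chromosome 17, starting at 33094273 and 32392430 (mm7). They may therefore not be separate differences. Probes of Rab44 and Dact2 are on that chromosome as well, farther away. Of the 100 genes of smallest p, 29 lay within 10 tested genes of another, against a median of 13 in 2000 random sets (permutation p = 0.001, one-sided). The count was 20 and 16 for the genes that differ most between mice of a genotype, which were ranked by size of difference rather than by p. Strain variants inherited in blocks are a candidate explanation on this mixed background, though neighbours expressed together would also raise the count. Variants shifting many genes beside the targeted Rb1 allele are argued against, since the 50 genes on each side were at the 39.9 percentile of such windows. That percentile is of a mean over the window, which could miss a few changed genes, so a small block there stays open. A variant under 1 probe stays open: 3 of 4 second probes showed little of the change, which choosing genes by the first probe gives as well.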

How the results depend on the processing

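Between mutant and null prostate the count stayed at 0 under every alternative that used all 4 arrays and adjusted p, the red channel alone included. Leaving out each array gave 0 to 163. An unadjusted p under 0.05 with at least 2-fold change gave 48, 167 and 162 genes in mutant against null, null against pool and mutant against pool. Null against pool gave 2 genes with the stricter filter, 2 with an intensity trend and robust moderation, and 0 to 559 when each array was left out. Mutant against pool gave 0 with Agilent processed signals, 1 with no background correction, 2778 with median centring, 0 with scaling between arrays, 0 with no filter, and 0 to 4 when each array was left out. Median centring moved the median of all genes to 0.42, 0.18 and 0.68 in the 3 comparisons. The replicate block gave 0 genes in mutant against pool and changed no other gene count. Replicate numbers do not pair the mice by the labels, and their deviations correlated at -0.00784 across genes.

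Called lists in mutant against null numbered 2 with median centring, 1 of them among the 8 reported, 0 with an estimated correlation, 0 with fry and 5 to 15 when each array was left out. In null against pool they numbered 10 with median centring, 5 of them among the 8 reported, 0 with an estimated correlation, 1 with fry and 8 to 13 when each array was left out. In mutant against pool they numbered 6 with median centring, 2 of them among the 10 reported while 7 of the 10 kept their direction, 0 with an estimated correlation and 0 with fry, and 8 to 10 when each array was left out. With the replicate block, 12, 11 and 12 lists were called in the 3 comparisons. Interferon response genes in null against pool turned from a median of 0.39 to -0.41 without null mouse 2, and were at 1.15 without null mouse 1. The shared direction stayed between 0.509 and 0.589 with other processing. Leaving out each array, an alternative added after the data were seen, gave 0.253 to 0.651, the lowest without null mouse 2 and below the 0.317 of simulated unchanged genotypes with 3 arrays. A fit leaving 1 mouse in a genotype assumes that it varies like the other genotype. The cause of these changes was not tested. The authors' deposited table holds no value per array, so that alternative was not run.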

Other observations

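Fixed lists not called in any comparison were the Rb and E2F family, E2F-linked apoptosis, DNA damage repair, stem and progenitor, epithelial-mesenchymal transition, lymphocyte, endothelial, glial and neuronal, hypoxia and glycolysis, and histone genes. Among stem and progenitor genes, the secreted chaperone gene Clu, taken as one of the brightest of its list, was at -2.04 ± 0.99 (SD, n = 2) in mutant and -2.12 ± 0.30 in null mice. The glycolysis enzyme gene Ldha was at 0.77 ± 0.13 in mutant and 0.34 ± 0.43 in null mice. The complement factor D gene Cfd, an adipocyte marker, was at -4.12 in null mouse 1 and 1.15 in null mouse 2.

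The sign of the median, the mean and the list test differed for 6 lists between the genotypes, 3 in null against pool and 5 in mutant against pool. Of these, 0 were called.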
